A study of Homo sapiens with 9 samples.

How the data were processed

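Total RNA was extracted with TRIzol from intracranial LN229 tumours taken at the terminal stage, and libraries were made with a full-length SMART-Seq kit followed by Nextera XT tagmentation, per the labels' protocols. That chemistry does not keep the strand, so overlapping and antisense genes cannot be separated. The submitters' processing notes name HISAT2, edgeR and GRCh38 without roles or versions. The counting tool, the annotation release, any gene filter and any separation of mouse from human reads are not given in the sources used here.

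The authors deposited log2 CPM values for 18364 genes by Entrez identifier and symbol, of which 224 had no symbol. The unit was read from the values, since the header does not give it. The lowest value was -2.786 in all 9 tumours, which is 0.145 CPM, and after removing it on the linear scale every tumour's values were whole multiples of 1 step. Taken over values under 5000 reads, 100% were whole within 0.1 read, so the deposited log2 values were converted back to whole reads for each gene. Totals were 19224552, 9151541, 16030692, 31468135, 3299325 and 3144861 reads in TAZ-4SA tumours 1 to 6 and 21576264, 17425672 and 17314672 reads in EV tumours 1 to 3. They cover the genes of the table. A floor of 3 reads corresponds to a mean of 0.419 CPM per TAZ-4SA library and 0.169 CPM per EV library. Reads without molecular identifiers are not independent molecules, so floors and counting intervals cover counting error only. A total of 18136 identifiers matched a RefSeq gene table of GRCh38, which gave coordinates.

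Tumours were assigned to TAZ-4SA (n = 6) or EV (n = 3) from the labels. The labels do not tie each tumour to an animal, so p-values measure the spread between these samples. No pair of tumours within a group agreed within sampling noise, and the closest, EV 1 and EV 2, had a chi-square per degree of freedom of 19.25. The main test was limma 3.58.1 (R 4.3.3) with an intensity trend and robust empirical Bayes on the deposited log2 values as they stand, for 15578 genes with a mean of at least 1 CPM over the 9 tumours, with Benjamini-Hochberg adjustment at 0.05. Fold changes are therefore on a log2 scale that includes the authors' prior of 0.145 CPM. They understate the change of genes close to that level in a whole group. Where only some tumours of a group had 0 reads, they can exceed the ratio of the mean CPM. A positive value means higher in TAZ-4SA. Gene lists, 28 in number and fixed before the data were examined, were tested with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 26 lists with at least 2 genes, and again with an estimated correlation and with fry. The WWTR1 level had an exact permutation test.

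Genes to name were chosen by a rule written beforehand. They were the 10 largest changes in each direction among called genes with a mean of at least 5 CPM, an official-style symbol and groups that did not overlap, a fixed set of TAZ, redox, iron and glucose genes, and up to 4 called members with the smallest p of each list. This gave 116 genes, some of which are not reported here.

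The fit was tested on simulated data, 5 runs with 200 changed genes each and the same number of genes at 0 reads per library as in the real tumours. Of the genes raised 8-fold, 92% were called, of those raised 4-fold 40.7% and of those raised 2-fold 1.6%. Of the genes lowered 8-fold, 13.5% were called and of those lowered 4-fold 6.4%. A call was therefore harder to reach for a fall than for a rise in these simulations, and the median number of false calls was 0. Before reads were drawn, every simulated tumour of both groups had the same spread. In the real tumours, genes at 10 to 50 CPM had a median SD of log2 CPM of 1.45 in TAZ-4SA and 0.27 in EV. The simulations therefore do not show how many calls are false at the real spread.

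Alternatives planned beforehand and run were pseudocounts of 0.1 and 2 CPM, median-of-ratios scaling, quantile normalization, no filter, a filter at a mean of 10 CPM, array weights, no robust step, each tumour left out, the replicate number as a block and a 2-fold minimum. Added after seeing the data were limma-voom on the recovered reads with and without weights per group, leaving out TAZ-4SA tumours 2, 3 and 4 or 5 and 6, tumours 1 to 3 of each group, EV libraries thinned to the detection of the TAZ-4SA libraries, and removal of a transcript length trend. Lengths were medians over protein-coding transcripts in GENCODE.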

Results

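RNA was sequenced from 9 tumours grown in the brains of nude mice from LN229, an established human glioblastoma cell line. The cells of 6 tumours carried TAZ-4SA, a form of the transcriptional co-activator TAZ, and those of 3 tumours carried the empty vector (EV). TAZ is encoded by WWTR1 and acts with TEAD transcription factors at the end of the Hippo pathway. The comparison addressed which genes change when TAZ is active in glioblastoma, in a series concerned with thioredoxin reductase and disulfidptosis, a form of cell death tied to disulfide stress in the actin cytoskeleton under glucose starvation. The deposited table gave log2 CPM, read counts scaled to library size, for 18364 genes, from which whole reads could be recovered. The TAZ-4SA tumours had between 3144861 and 31468135 recovered reads, and the EV tumours between 17314672 and 21576264.

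The TAZ-4SA libraries detected fewer genes than the EV libraries. Between 2990 and 7365 genes had 0 reads in a TAZ-4SA tumour, against 505 to 622 in an EV tumour. TAZ-4SA tumour 4 had the most reads of the 9 and 6573 genes at 0 reads. Among genes with 10 to 20 CPM in the other tumours of the group, the share at 0 reads lay between 0.8% in TAZ-4SA tumour 5 and 27.9% in TAZ-4SA tumour 2, and it was 0.0% in each EV tumour. Pairwise correlations of log2 CPM across genes lay between 0.632 and 0.776 within TAZ-4SA and between 0.955 and 0.985 within EV. These correlations describe libraries, since genes are not independent replicates.

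**Figure D1:**
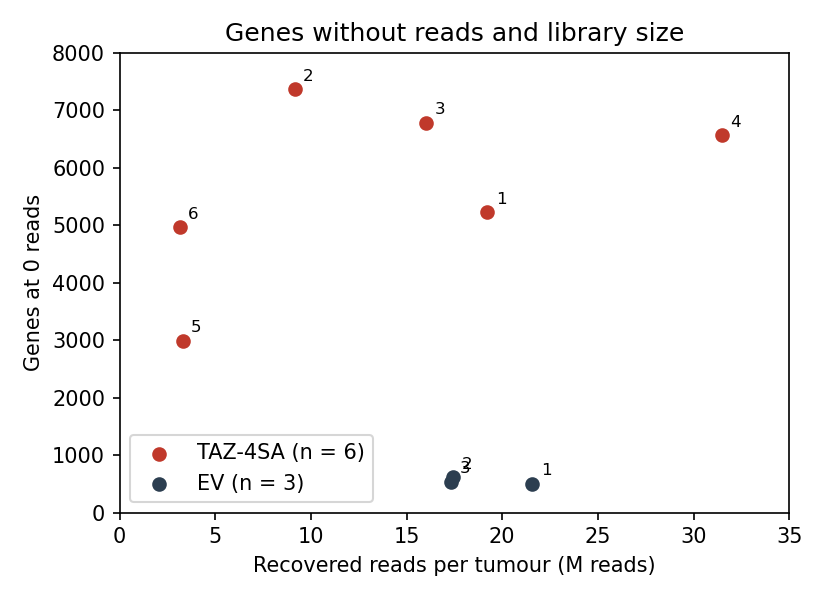
Number of genes at 0 reads (vertical axis) against recovered reads (horizontal axis, M reads) for each tumour, with the replicate number beside each point. The 6 TAZ-4SA tumours (red) sit between 2990 and 7365 genes and the 3 EV tumours (dark) between 505 and 622, at overlapping read totals.

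WWTR1 itself (Entrez gene 25937), on chromosome 3 from 149517235 to 149724788 (GRCh38, protein-coding), was higher in the TAZ-4SA tumours. The level of WWTR1 was 331 ± 74.6 CPM (SD, n = 6) in TAZ-4SA and 120 ± 3.17 CPM (SD, n = 3) in EV, a log2 difference of 1.44. All TAZ-4SA values lay above all EV values, and the exact two-sided permutation test over the 84 ways of choosing 3 of 9 tumours gave p = 0.02381, the smallest it can give. The groups did not overlap for 32% of the 15578 genes tested, where chance gives 2.38%, so separation does not single out WWTR1. Reads from an introduced human sequence and from the resident gene cannot be told apart in a table of gene values. YAP1, the paralog of TAZ, stood at 28.2 ± 19.3 CPM in TAZ-4SA and 15.1 ± 3.01 CPM in EV (limma adjusted p = 0.6676).

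Established YAP/TAZ target genes rose as a group. Of 22 members tested, 17 were higher in TAZ-4SA past an adjusted p of 0.05 in the limma fit, 0 were lower and 5 were not called, and adjusted over the list alone 18 were higher. ANKRD1, a nuclear ankyrin-repeat protein on chromosome 10 from 90912096 to 90921087, had the largest log2 fold change of the list at 9.63 ± 0.47 (SE), from 0.239 ± 0.0489 CPM in EV to 330 ± 143 CPM in TAZ-4SA. CCN1, a secreted matricellular protein on chromosome 1 from 85580761 to 85583950, rose from 77.4 ± 95.8 to 1787 ± 394 CPM. The receptor tyrosine kinase gene AXL rose from 72.4 ± 13.2 to 728 ± 408 CPM, and MYOF, which encodes a membrane-repair protein, rose from 3.52 ± 1.47 to 560 ± 145 CPM. CCN2 was also called higher (log2 fold change 1.80 ± 0.45, limma adjusted p = 0.01442), although its EV values of 167 ± 160 CPM overlapped those of TAZ-4SA, and it was not called without EV replicate 1 (limma adjusted p = 0.0684) or EV replicate 2 (limma adjusted p = 0.09003). Its log2 fold change was 2.55 without EV replicate 3. The log2 fold change of CCN1 was 5.28, and it was 4.66 without EV replicate 2 and 6.31 without EV replicate 3. The list passed camera, a competitive test against the other genes, with an adjusted p of 4.178e-17 at a preset correlation and an adjusted p of 0.02313 with an estimated correlation.

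In the list of Hippo pathway genes and TEAD factors 13 of 24 members were higher, 1 lower and 10 not called, and 14 higher and 2 lower adjusted over the list alone. The higher members include WWTR1, the gene of the construct itself, which also entered the camera test. TEAD1, a DNA-binding partner of TAZ, rose from 38.7 ± 9.94 to 357 ± 47.6 CPM, while TEAD2, TEAD3 and TEAD4 were not called (log2 fold changes -1.07, 0.014 and -0.59). WWC2 rose from 11.2 ± 0.931 to 153 ± 58.3 CPM, WWC1 from 35.1 ± 4.25 to 170 ± 79.5 CPM, and VGLL3 from 3.72 ± 0.901 to 72.1 ± 54.7 CPM. AMOTL1 was the lower member, with a log2 fold change of -1.32. The camera adjusted p was 3.857e-06, and with an estimated correlation the adjusted p was 0.02313.

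**Figure D2:**
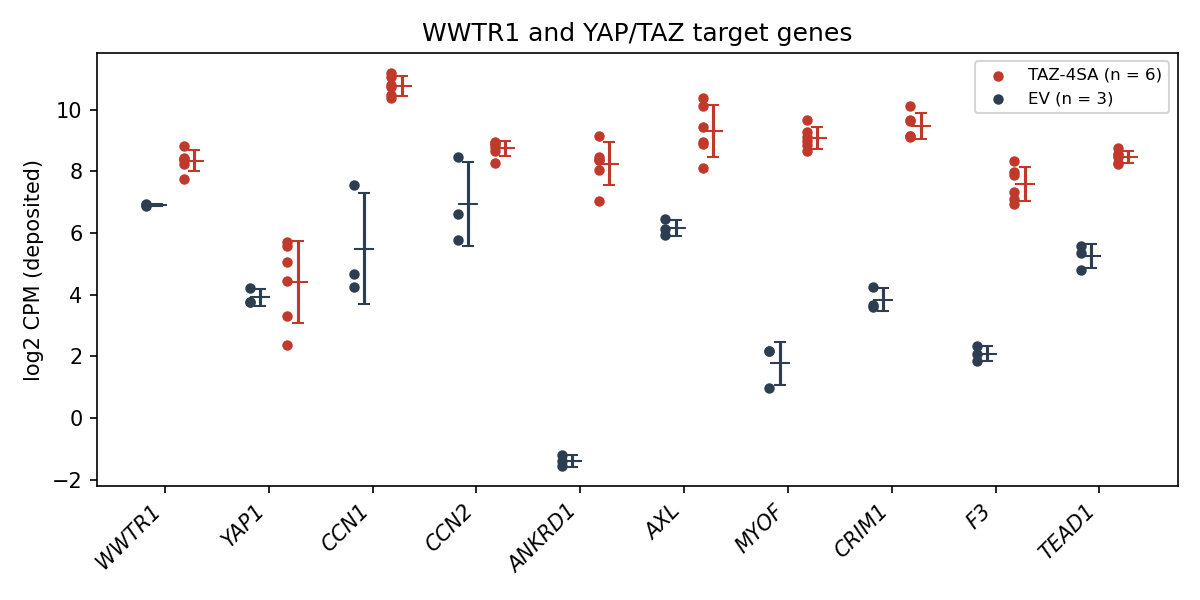
Deposited log2 CPM (vertical axis) of WWTR1, YAP1 and 8 further genes in each TAZ-4SA (red, n = 6) and EV (dark, n = 3) tumour, as points, with the mean and SD beside them. The 6 TAZ-4SA values of WWTR1, CCN1, ANKRD1, AXL, MYOF, CRIM1, F3 and TEAD1 lie above the 3 EV values, while those of YAP1 and CCN2 overlap.

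Over all genes, 1405 were higher and 2079 lower in TAZ-4SA among 15578 genes tested with limma at an adjusted p of 0.05. The strongest rises were in genes close to silent in the EV tumours. MME, which encodes the cell-surface peptidase neprilysin (chromosome 3 from 155024202 to 155183729), rose from 0.195 ± 0.0884 to 498 ± 97.8 CPM, and the carboxypeptidase gene CPA4 from 2.61 ± 0.482 to 1284 ± 278 CPM. INHBA, a subunit of activin, rose from 0.934 ± 0.606 to 295 ± 155 CPM (log2 fold change 8.17, and 7.54 without EV replicate 1), AOX1 from 0.294 ± 0.0535 to 134 ± 49.9 CPM, the long non-coding RNA UCA1 from 0.121 ± 0.117 to 159 ± 44.4 CPM, and the cytokine receptor gene IL7R from 0.113 ± 0.156 to 133 ± 68.8 CPM. NPPB had 3 reads over the EV tumours and 5799 over the TAZ-4SA tumours, a depth-adjusted ratio of 1313 with a 95% counting interval of 449 to 6370. MARCHF4 had 2 EV reads and a ratio of 2230 (617 to 18421). SPANXB1 also had 2 EV reads and a ratio of 5369 (1486 to 44336), but it belongs to a family of near-identical copies on chromosome X, so its reads could stem from relatives. These intervals cover counting error only.

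Of the 10 largest falls, 4 were in genes without a read in any TAZ-4SA tumour. COL9A1, a cartilage collagen chain on chromosome 6 from 70215061 to 70303084, stood at 814 ± 84.4 CPM in EV and was at least 1944-fold lower in TAZ-4SA, against a floor of 3 reads per library. The extracellular superoxide dismutase gene SOD3 was at least 782-fold lower, MGP, an inhibitor of calcification, at least 506-fold, and the SOXE factor gene SOX8 at least 284-fold. These bounds cover counting error only. In TAZ-4SA tumour 2, 27.9% of genes with 10 to 20 CPM in the other TAZ-4SA tumours had 0 reads. The true falls could therefore be smaller than these bounds. A2M, at 1294 ± 261 CPM in EV, had a log2 fold change of -9.61 ± 1.86, which was -10.55 without TAZ-4SA replicate 4, -10.22 without replicate 1 and -8.92 without replicate 2, 3 or 6, and IGFBP2, an insulin-like growth factor binding protein fell from 484 ± 73.1 to 2.72 ± 4.24 CPM, with 0 reads in 3 and 4 TAZ-4SA tumours. The log2 fold change of IGFBP2 moved from -9.75 to -10.56 and -10.50 without TAZ-4SA replicates 5 and 6. CPXM1, F5, ITIH6 and the gene listed as ECMXP had EV means between 163 and 234 CPM and TAZ-4SA means under 1 CPM. Leaving out TAZ-4SA replicate 5 moved CPXM1 from -9.77 to -10.63 and ECMXP from -9.49 to -10.13 on the log2 scale, and leaving out replicate 1 moved F5 from -9.69 to -10.33. Of the genes called lower, 1292 had 0 reads in at least 1 TAZ-4SA tumour and 279 in all 6. The split between directions depended on scaling, with 1920 higher and 1624 lower after quantile normalization, where the median log2 fold change over all genes tested moved from -0.85 to -0.15. Leaving out EV replicate 1, 2 or 3 left 1699, 1651 and 2019 genes called in all, and 90, 90 and 97 of the 109 named genes that were called. Without TAZ-4SA tumours 2, 3 and 4, which had the most genes at 0 reads and were left out after seeing the data, 1893 genes were higher and 2256 lower.

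In the mesenchymal glioblastoma list 13 of 32 members were higher, 4 lower and 15 not called (15 higher and 5 lower adjusted over the list alone). CAV1, a caveolar coat protein gene, rose from 31.8 ± 5.34 to 1083 ± 222 CPM, the receptor gene MET from 5.77 ± 1.37 to 190 ± 23.1 CPM and CD44 from 97.6 ± 14.0 to 309 ± 69.9 CPM. The 4 lower members were CHI3L1, TIMP1, PDPN and SPP1. CHI3L1, a secreted glycoprotein often used as a mesenchymal marker, had 156 ± 196 CPM in EV and 0 reads in each TAZ-4SA tumour, at least 373-fold lower. EV replicate 2 carried that bound, with 381 CPM, and without it CHI3L1 had an EV mean of 43.5 CPM and was at least 104-fold lower. Both bounds cover counting error only, so the true fall could be smaller. The camera adjusted p was 3.073e-06, and with an estimated correlation the adjusted p was 0.02313.

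Of 34 extracellular matrix and EMT genes, 15 were higher, 1 lower and 18 not called, with 15 higher and 2 lower adjusted over the list alone. THBS1, encoding thrombospondin, rose from 47.7 ± 7.64 to 2804 ± 628 CPM, COL1A1 from 113 ± 42.5 to 3206 ± 1264 CPM, and the transcription factor gene SNAI2 from 13.6 ± 2.59 to 174 ± 39.4 CPM. The list passed camera with an adjusted p of 0.0001035, but had an adjusted p of 0.171 with an estimated correlation. Among 32 genes of the actin cytoskeleton and WAVE complex tied to disulfidptosis, 13 were higher, 2 lower and 17 not called, and the counts adjusted over the list alone were the same. FLNC, a filamin gene, rose from 3.92 ± 2.30 to 309 ± 143 CPM, MYH9, a non-muscle myosin heavy chain gene, from 466 ± 20.1 to 3155 ± 1274 CPM and IQGAP1 from 54.3 ± 1.15 to 403 ± 73.9 CPM, while ARPC1B and MYL6 were lower. Its camera adjusted p was 3.422e-05, with an adjusted p of 0.1225 with an estimated correlation. Of 15 chemokine and cytokine genes, 3 were higher (IL6, IL11 and LIF) and 2 lower (SPP1 and CX3CL1), or 6 and 2 adjusted over the list alone, with a camera adjusted p of 0.005537 and an adjusted p of 0.2203 with an estimated correlation. IL6 was not called without any 1 of the EV replicates (limma adjusted p = 0.05784, 0.09228 and 0.07232 without EV 1, 2 and 3). LIF was not called without TAZ-4SA replicate 1 or 5 (limma adjusted p = 0.06563 and 0.06126) or EV replicate 1 or 2 (limma adjusted p = 0.1594 and 0.1025), nor CX3CL1 without EV replicate 3 (limma adjusted p = 0.05079). The log2 fold change of IL11 was 3.52, and 4.12 without EV replicate 2, and that of CX3CL1 was -6.25, and -6.84 without TAZ-4SA replicate 6.

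The cystine, glutathione and thioredoxin genes, which bear on the thioredoxin reductase question of the series, divided. SLC7A11, the cystine-importing subunit of system xc-, rose from 3.06 ± 0.472 to 45.5 ± 10.1 CPM (log2 fold change 3.82 ± 0.54, limma adjusted p = 0.0005141; chromosome 4 from 138164097 to 138242349). TXNRD1, cytosolic thioredoxin reductase, rose from 61.5 ± 6.66 to 266 ± 120 CPM (log2 fold change 1.99 ± 0.37, limma adjusted p = 0.002732; chromosome 12 from 104215779 to 104350307). GCLM, the modifier subunit of glutamate-cysteine ligase, rose from 6.95 ± 1.03 to 67.0 ± 42.1 CPM. SLC3A2, the heavy chain paired with SLC7A11, stood at 217 ± 95.4 CPM in TAZ-4SA and 207 ± 96.1 CPM in EV, and its log2 fold change of 0.050 turned to -0.039 under median-of-ratios scaling and to -0.19 without EV replicate 1. TXN was at 150 ± 99.2 and 80.2 ± 6.63 CPM, TXNIP at 130 ± 61.7 and 441 ± 340 CPM, and GPX4 at 115 ± 45.4 and 181 ± 18.3 CPM in TAZ-4SA and EV, none of them called. The log2 fold change of TXNIP was -1.93, and it was -1.22 without TAZ-4SA replicate 3 and -1.33 without EV replicate 3. Over the list, 7 of 36 members were higher and 3, the peroxidase genes GPX1, PRDX2 and PRDX5, were lower, in both adjustments, and the list did not pass camera (adjusted p = 0.1813).

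Of 32 NRF2 targets, 5 were higher and 5 lower (5 and 7 adjusted over the list alone), and the camera adjusted p was 0.2334. AKR1C1, an aldo-keto reductase gene of that list, fell from 97.4 ± 32.3 to 0.743 ± 1.56 CPM, with 0 reads in 4 TAZ-4SA tumours, and its log2 fold change of -8.15 was -8.88 without TAZ-4SA replicate 1. In the pentose phosphate and NADPH list 3 of 24 genes were higher and 4 lower (5 and 6 adjusted over the list alone; camera adjusted p = 0.3572). PGD fell from 113 ± 8.91 to 51.0 ± 10.4 CPM but was not called without EV replicate 1, 2 or 3 (limma adjusted p = 0.1103, 0.07786 and 0.07595). IDH2, also lower, was not called without EV replicate 1, 2 or 3. H6PD, also lower, and MTHFD2, higher, were not called without EV replicate 1 or 2. The ferroptosis and iron list had 3 of 29 higher and 3 lower in both adjustments (camera adjusted p = 0.4172). ACSL4, which primes membrane lipids for peroxidation, rose from 13.2 ± 0.656 to 121 ± 42.4 CPM, and the transferrin receptor gene TFRC from 41.6 ± 12.8 to 178 ± 52.4 CPM. The transferrin gene TF fell from 162 ± 25.4 to 2.07 ± 4.94 CPM, with 0 reads in 4 TAZ-4SA tumours. Its log2 fold change was -8.79 ± 1.57 (-9.81 without TAZ-4SA replicate 4). The lipoxygenase gene ALOX15 had a log2 fold change of -5.12 ± 0.97, with 0 reads in 5 TAZ-4SA tumours.

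**Figure D3:**
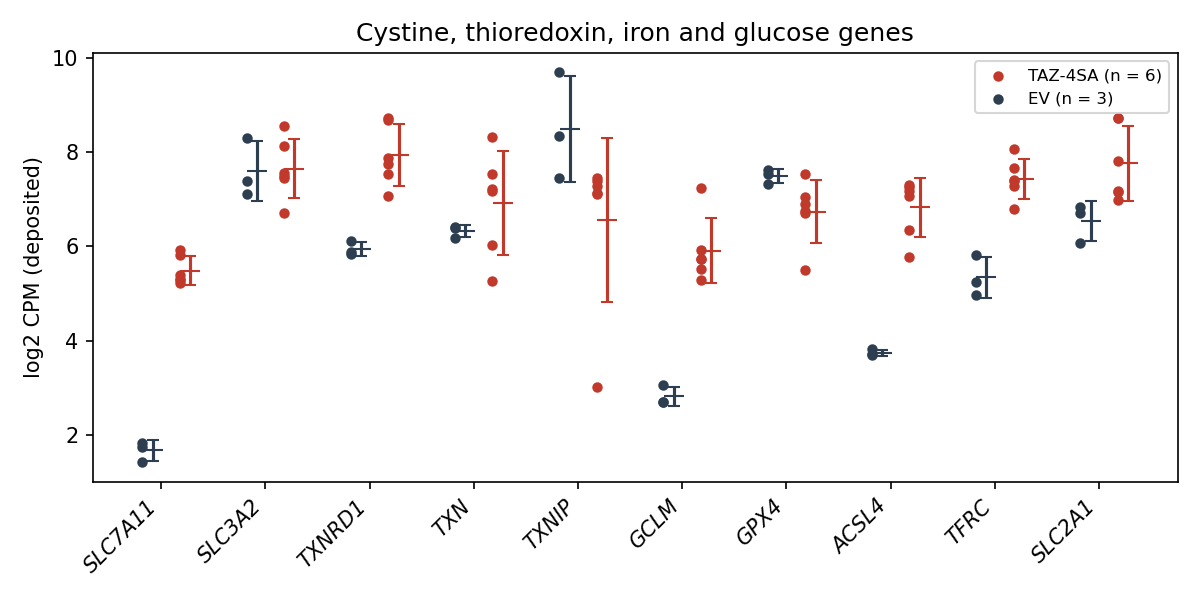
Deposited log2 CPM (vertical axis) of 10 genes of cystine import, thioredoxin, glutathione, iron and glucose handling in each TAZ-4SA (red, n = 6) and EV (dark, n = 3) tumour, as points, with the mean and SD beside them. SLC7A11, TXNRD1, GCLM, ACSL4 and TFRC were called higher in TAZ-4SA, and SLC3A2, TXN, TXNIP, GPX4 and SLC2A1 were not called.

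Of 26 glucose transport and glycolysis genes, 3 were higher and 0 lower in both adjustments (camera adjusted p = 0.1758). LDHA, lactate dehydrogenase A, rose from 648 ± 69.5 to 1203 ± 274 CPM, PDK1 from 13.6 ± 2.26 to 69.3 ± 28.8 CPM and the monocarboxylate transporter gene SLC16A1 from 47.9 ± 3.66 to 107 ± 20.7 CPM. SLC2A1, the glucose transporter GLUT1, stood at 247 ± 140 CPM in TAZ-4SA and 95.1 ± 25.1 CPM in EV, just outside the threshold (limma adjusted p = 0.06269), and was called without TAZ-4SA replicate 2 (limma adjusted p = 0.0417). LDHA was not called without EV replicate 1, 2 or 3 (limma adjusted p = 0.1234, 0.09819 and 0.05472) or TAZ-4SA replicate 1 (0.05177), SLC16A1 was not called without EV replicate 1 (0.07639) or 2 (0.08822), and the glucose list passed camera without TAZ-4SA replicate 6 (adjusted p = 0.04556). Of 30 hypoxia response genes 7 were higher and 1 lower, or 8 and 3 adjusted over the list alone, among them ADM, which rose from 24.5 ± 17.0 to 225 ± 76.0 CPM. That list had a camera adjusted p of 0.0177, an adjusted p of 0.4507 with an estimated correlation and an adjusted p of 0.07469 after quantile normalization. It did not pass without TAZ-4SA replicate 3 (adjusted p = 0.06043). The median log2 fold change of the hypoxia list was 0.025, where the median over all genes tested was -0.85. The list was therefore higher relative to the other genes and did not rise as a whole. The ATF4 and amino acid stress list had 6 of 30 genes higher and 1 lower (7 and 1 adjusted over the list alone; camera adjusted p = 0.156), with STC2 rising to 236 ± 52.9 CPM, a log2 fold change of 4.26 ± 0.30. The ATF4 list passed camera without EV replicate 3 (adjusted p = 0.04863).

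Of 25 proneural glioblastoma genes, 7 were lower and 2 higher, or 11 and 2 adjusted over the list alone. SOX10, a neural crest and oligodendrocyte transcription factor gene on chromosome 22 from 37972312 to 37984555, fell from 1698 ± 187 to 45.6 ± 20.3 CPM, and the receptor gene ERBB3 from 1347 ± 131 to 73.4 ± 41.4 CPM. NES, the intermediate filament gene nestin, fell from 1324 ± 35.1 to 158 ± 60.5 CPM, while NCAM1 rose from 19.5 ± 2.19 to 62.5 ± 26.3 CPM. The camera adjusted p was 0.04473, with an adjusted p of 0.5092 with an estimated correlation. Of 8 oligodendrocyte markers, 3 were lower and 0 higher (5 and 0 adjusted over the list alone), namely GJB1, MAG and MYRF, with a camera adjusted p of 0.03102 and an adjusted p of 0.4507 with an estimated correlation. The proneural list did not pass without TAZ-4SA replicate 1, 3 or 4 (adjusted p = 0.08153, 0.09281 and 0.07195), nor the oligodendrocyte list without TAZ-4SA replicate 1 (adjusted p = 0.06814), and NCAM1 was not called without EV replicate 1, 2 or 3 (limma adjusted p = 0.07074, 0.07028 and 0.07827). MAG was not called without EV replicate 1 (limma adjusted p = 0.05174). The summed level of 12 oligodendrocyte markers was 459 CPM in TAZ-4SA tumour 5 and 323 CPM in TAZ-4SA tumour 6, against 53.7 to 137 CPM in the other TAZ-4SA tumours and 842 to 938 CPM in the EV tumours. At least 1 TAZ-4SA tumour had 0 reads for 2 of the 7 lower proneural genes and for 2 of the 3 lower oligodendrocyte markers.

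Of 34 cytosolic ribosomal protein genes, 22 were lower, 0 higher and 12 not called, and 24 were lower adjusted over the list alone. RPL13A fell from 2585 ± 211 to 862 ± 230 CPM and RPL7 from 680 ± 124 to 186 ± 46.5 CPM, with reads in each tumour. The camera adjusted p was 0.001132, with an adjusted p of 0.4507 with an estimated correlation. Without TAZ-4SA tumours 5 and 6, a choice made after seeing the data, the camera adjusted p was 0.05902. Of 32 nuclear oxidative phosphorylation genes, 7 were lower and 0 higher (11 and 0 adjusted over the list alone; camera adjusted p = 0.1813), including NDUFV1, a complex I subunit gene, which fell from 424 ± 15.5 to 120 ± 61.3 CPM. Among the lower members, COX4I1 was not called without EV replicate 1, 2 or 3, nor NDUFB10 without EV replicate 1 or 2.

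**Figure D4:**
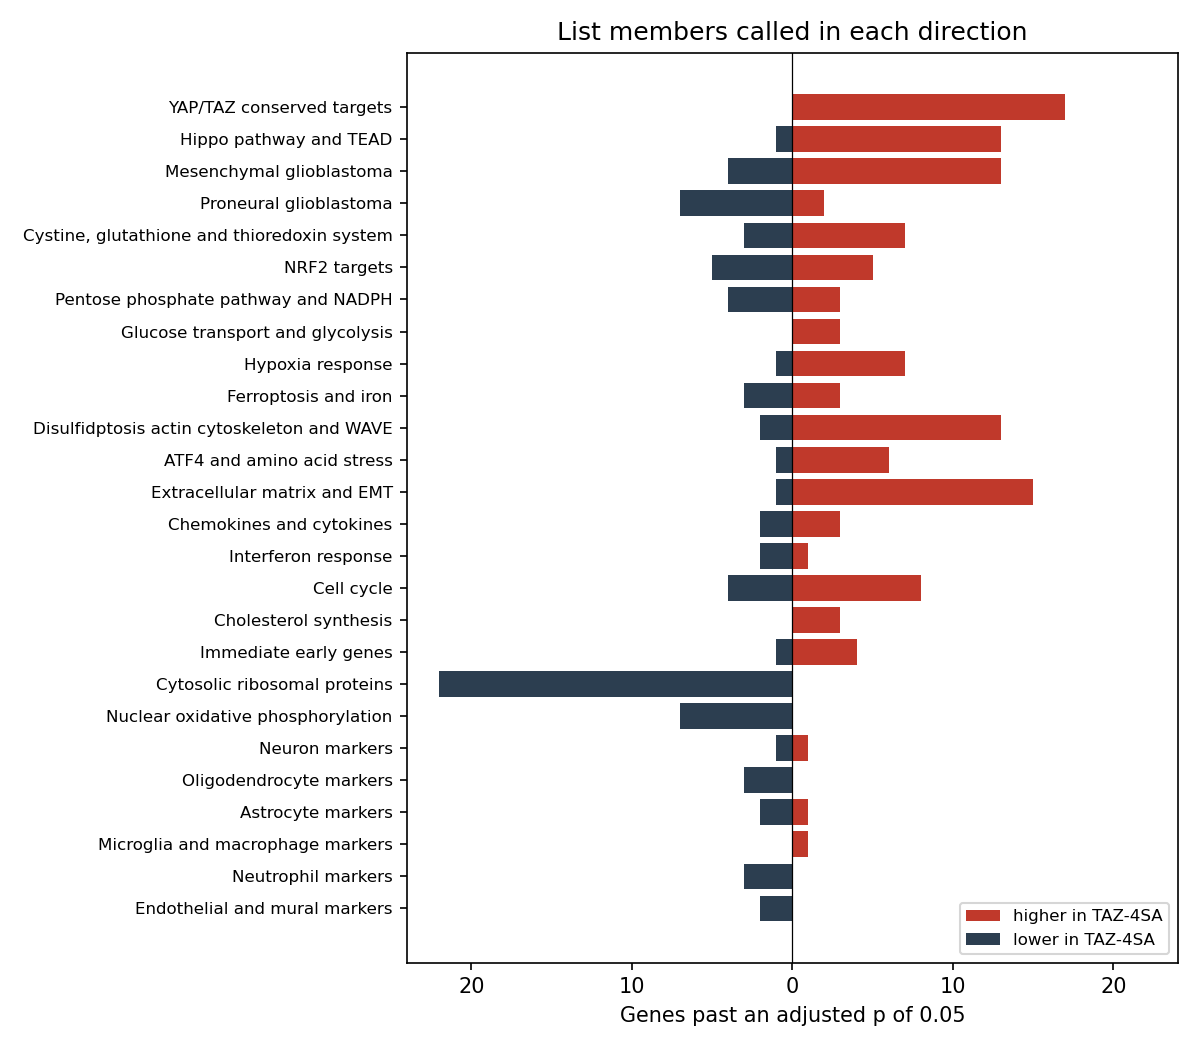
Number of genes of each fixed list past an adjusted p of 0.05 in the limma fit (horizontal axis), to the right for genes higher and to the left for genes lower in TAZ-4SA. The YAP/TAZ targets have 17 genes to the right and 0 to the left, and the cytosolic ribosomal proteins 22 to the left and 0 to the right.

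Proliferation and stress genes went both ways. Of 34 cell cycle genes, 8 were higher, among them CCND1 and CCNA2, and 4 lower, among them MCM7 and MCM3 (9 and 5 adjusted over the list alone; camera adjusted p = 0.1813). Of 20 immediate early genes, 4 were higher and 1, NR4A1, lower (5 and 1 adjusted over the list alone; camera adjusted p = 0.2283, and 0.04076 without EV replicate 3). Of 24 cholesterol synthesis genes, 3 were higher in both adjustments (camera adjusted p = 0.1758). Of 28 interferon response genes, 1 was higher and 2 lower (1 and 1 adjusted over the list alone; camera adjusted p = 0.7581). The camera direction was higher while the list's median log2 fold change was negative for the cystine and thioredoxin, NRF2, NADPH, ferroptosis, ATF4, cell cycle, cholesterol, immediate early, neuron and microglia lists, where the median over all genes tested was -0.85.

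Markers of cells that a brain tumour could contain were also measured. The host cells of these tumours are mouse cells. Reads counted for these human genes therefore came from LN229 cells or from mouse reads aligned to human genes, which cannot be told apart here. Of 21 neuron markers, 1 was higher (SYT1) and 1 lower (THY1) in both adjustments (camera adjusted p = 0.1813). SYT1 was at 78.7 ± 73.4 CPM in TAZ-4SA, and THY1 was not called without EV replicate 1, 2 or 3 (limma adjusted p = 0.06072, 0.06058 and 0.07765). The summed level of the 22 neuron markers in the table was 1805 CPM in TAZ-4SA tumour 5 and 2042 CPM in TAZ-4SA tumour 6, against 248 to 723 CPM in the other TAZ-4SA tumours and 378 to 584 CPM in the EV tumours. Of 13 astrocyte markers, 1 was higher and 2 lower in both adjustments (camera adjusted p = 0.5271), and the summed level of 14 astrocyte markers was 789.5 CPM in TAZ-4SA tumour 5, 265 to 409.6 CPM in the other TAZ-4SA tumours and 726 to 889.5 CPM in the EV tumours. Of 11 microglia and macrophage markers, 1, CD68, was higher (camera adjusted p = 0.5399), of 7 neutrophil markers 3 were lower, all with 0 reads in each TAZ-4SA tumour (camera adjusted p = 0.07804, and 0.03456 and 0.04839 without EV replicates 1 and 3), and of 10 endothelial and mural markers 2 were lower (camera adjusted p = 0.3069), with the same counts adjusted over each list alone. The lower endothelial and mural members were ERG and CSPG4, the second of which is also expressed by glial precursors. ERG was not called without EV replicate 1, 2 or 3 (limma adjusted p = 0.06366, 0.1018 and 0.05045). The lymphocyte and erythroid list had 1 gene to test, CD8A, which was lower, and the mitochondrially encoded list was not analysed here.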

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

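The comparison of outlying tumours was fixed beforehand, and the tests of library depth and of genes silent in all TAZ-4SA tumours were chosen only after the results they bear on were seen. A tumour's value was called outlying when its gap to the nearest of the 6 TAZ-4SA tumours, as a share of their range, passed the 95% critical value of Dixon's test. This held in 13 of 119 sets of values, where chance gives about 1 in 20. In 5 of the 13 (CPXM1, ECMXP, ERG, ALOX15 and SLC7A3) the other 5 tumours had 0 reads, so that any read meets the criterion, which leaves 8. Of those 8, ITIH6, F5 and TF also rest on the floor, with 0 reads in 4 TAZ-4SA tumours each. Genes at 0 reads in all 6 TAZ-4SA tumours are among the 119 sets and could not be flagged. The flags that do not rest on the floor are about as many as chance gives.

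TAZ-4SA tumour 5 had the fewest genes at 0 reads of the TAZ-4SA tumours, at 2990. It stood apart for ITIH6 (log2 CPM 0.34), CPXM1 (2.37), ECMXP (1.07) and ERG (-0.022), in each case above tumours at or near the floor of -2.786. It was also lowest for CD44 at 7.53, where the others lay between 8.24 and 8.65, and highest for IRF9 at 6.43, where the others lay between 4.91 and 5.33. TAZ-4SA tumour 3 was far below the others for TXNIP, at 3.01 against 7.10 to 7.44, and below them for CCND1, at 8.59 against 9.02 to 9.24. Its SLC7A3 value of -2.28 was the only one above the floor. TAZ-4SA tumour 1 was highest for F5 at 1.19, tumour 2 for GCLM at 7.25 against 5.29 to 5.93, tumour 4 for TF at 3.62 and tumour 6 for ALOX15 at -1.15.

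More genes were called lower than higher, and the low-abundance genes carried that excess, with 851 lower and 1 higher at a mean of 1 to 5 CPM. With every library thinned to 3144861 reads, the EV libraries had at most 1519 genes at 0 reads and the TAZ-4SA libraries at least 3004, so depth does not account for the difference in detection. The 1519 narrowly missed the stricter bound of 1502 set for that test, and the reading rests on the groups not overlapping, with EV between 1433 and 1519. Of 1038 genes under 10 CPM called lower, 23.6% stayed called lower when EV was thinned to the detection of the TAZ-4SA libraries. Fewer captured molecules in the TAZ-4SA libraries may explain the others. Thinning also makes a real fall harder to call, so the lost calls cannot decide this. Of 1041 genes at 10 CPM and over, 73.7% stayed called lower. With an EV mean of at least 10 CPM, 50 genes had 0 reads in all 6 TAZ-4SA tumours, where independent non-detection predicts 0.000734. Random loss of molecules therefore does not account for most of those. Both tests assume that genes are lost independently in each library. Loss of the same genes in every TAZ-4SA library was not tested and cannot be excluded. A difference with TAZ-4SA stays open, untested.

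Of 34 ribosomal protein genes 22 were called lower and 12 were not called, and the list lost its call with an estimated correlation (adjusted p = 0.4507). With the transcript length trend removed 16 stayed called lower at a median log2 fold change of -0.76, and under the other scalings at least 18 did, so neither length nor normalization accounts for the whole fall. Other short and abundant genes, 36 in number, had a median of -0.11 with a 95% bootstrap interval of -0.65 to 0.35. A biological difference between the groups stays open as a hypothesis.

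Chance assignment of tumours was unlikely for the gene counts, although 1 of 84 is the smallest share this test can give. The EV libraries also detected more genes, so the splits cannot tell an effect of TAZ-4SA from a difference between libraries. Of the 84 splits of the 9 tumours, only the real one (1 of 84) gave as many as 3484 genes, with 280 the highest of the others, and the same held for the 1405 higher genes (highest other 276) and the 2079 lower genes (highest other 6). Chance assignment cannot be excluded for the number of lists, since 14 of the 84 splits gave 10 or more, the highest other being 14.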

How the results depend on the processing

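The voom, thinned, length and grouped leave-out settings were added after seeing the data. The planned edgeR and DESeq2 alternatives on recovered reads were not run, and limma-voom was run on those reads. Of 109 named genes called, none reversed under any setting, and between 81 (replicate block) and 109 kept their call. Most were chosen for large or clear changes in this same fit, which favours that outcome. Over all genes, 799 of the 1405 higher calls and 851 of the 2079 lower calls were kept without EV replicate 2. Against 3484 genes called (1405 higher, 2079 lower), array weights gave 8161 (2531 and 5630) and voom with group weights 6926 (2181 and 4745). Voom without group weights gave 3646 lower, no filter 3384 and the 10 CPM filter, which tests fewer genes, 967. EV thinned to all genes at 0 or to detection at 10 to 20 CPM gave 1069 and 1095 lower. Apart from the filters and thinning, the cause was not tested. With 1 tumour left out, totals ranged from 1651 to 4275, higher genes from 799 to 1685, lower genes from 852 to 2688, WWTR1 from 1.34 to 1.55 (exact permutation p = 0.07143 without an EV tumour, the smallest possible with 2 EV tumours), SLC3A2 from -0.19 to 0.40 and the interferon list's adjusted p from 0.4995 to 0.8695. SLC3A2 was -0.039 under median-of-ratios scaling. Same-numbered tumours share only a number (correlations of deviations 0.031, 0.004 and -0.047). With the replicate block 562 genes were higher, and WWTR1 differed by 1.41 (exact p = 0.25, the smallest possible with 3 pairs). The neuron list turned with that block (adjusted p = 0.9214), as it did without TAZ-4SA tumours 5 and 6 (0.9333). The estimated correlation left 3 of 10 lists. Uncalled lists turned direction for interferon without a filter (0.8924), with array weights (0.8178), without TAZ-4SA tumours 2, 3 and 4 (0.5776), without TAZ-4SA replicate 3 (0.7915) and without EV replicate 2 (0.5923), and under fry for NADPH (0.7001), ferroptosis (0.5346) and microglia (0.7706). A floor of 3 reads was 0.419 CPM on average in TAZ-4SA, but detection did not follow depth there. TAZ-4SA tumour 4, with 31468135 reads, had 6573 genes at 0 reads, and TAZ-4SA tumour 5, with 3299325 reads, had 2990.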

Other observations

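The tests of gene families and of the lineage lists below were chosen only after the main comparison was seen. Keratins were the family that stood out, with 3 of 16 higher and 0 lower (camera adjusted p = 0.004487, adjusted p = 0.3447 with an estimated correlation). KRT81 had a log2 fold change of 7.60 and KRT80 of 4.68, and KRT18 of 1.22. Collagen chains divided, with 6 of 40 higher and 13 lower. COL1A1, COL17A1, COL8A1, COL5A1, COL4A1 and COL12A1 were higher, while COL2A1, COL9A1, COL9A2, COL9A3, COL11A1, COL11A2, COL16A1, COL18A1, COL20A1, COL22A1, COL26A1, COL27A1 and COL28A1 were lower. COL10A1, a chain of hypertrophic cartilage, had a log2 fold change of 3.81 and was not called (limma adjusted p = 0.1233). Integrin subunits divided too, with 4 of 26 higher (ITGB1, ITGA3, ITGAV and ITGB2) and 6 lower, among them ITGA10, ITGA9 and ITGB4. Neither family passed camera (adjusted p = 0.4506 for both). Heat shock proteins had 6 of 21 higher and 1 lower (adjusted p = 0.05606). Protocadherins (0.2404), solute carriers (0.5124), zinc finger proteins (0.2404), proteasome subunits (0.4506) and mitochondrial ribosomal proteins (0.2404) did not pass either.

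SOX10 stood at 1698 CPM in EV, and PMEL, a melanosome protein gene, at 50.6 CPM in EV and 1.16 CPM in TAZ-4SA, whereas SOX9 and MITF were higher in TAZ-4SA. Lists of cartilage and of neural crest genes were then tested, and the cartilage list shares COL10A1 and COL27A1 with the collagen chains. Of 18 cartilage genes 12 were lower and 0 higher (camera adjusted p = 3.848e-05, adjusted p = 0.05902 with an estimated correlation), with a median log2 fold change of -4.13, or -3.95 with the gene at 0 reads in all TAZ-4SA tumours set at its bound. Of 19 neural crest, Schwann and melanocyte genes 8 were lower and 1 higher (camera adjusted p = 0.02017, adjusted p = 0.1205 with an estimated correlation), the higher one being L1CAM at 485 CPM in TAZ-4SA and 146 CPM in EV. The estimated correlation keeps both open, so lower levels of these groups with TAZ-4SA are a hypothesis, and RNA of other cells in the EV tumours was not excluded. At least 1 TAZ-4SA tumour had 0 reads for 9 of the 12 lower cartilage genes, and whether both groups descend from 1 population of LN229 cells was not tested.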
